A study of Danio rerio with 15 samples.

How the data were processed

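The data are RNA sequencing libraries from tissue of zebrafish larvae that carry green fluorescent endothelium and red fluorescent erythroid cells. Per the labels, venous endothelium behind the anal pore was injured with a laser, and the thrombus that formed was sampled 1, 3, 6 or 12 h later; the control was venous tissue with no injury. The tissue was cut into 20 frozen sections of 20 µm and cells were taken by laser-capture microdissection. There were 15 libraries in 5 groups of 3. The labels do not tie captured tissue to animals, so libraries may share an animal or pool several. The p-values then measure only the spread between these libraries, which may be technical, and may be too small. No uninjured tissue was taken at the later times.

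Per the submitters' processing notes and the labels' protocols, paired-end HiSeq 4000 reads were aligned with HISAT to the GRCz11 genome of Ensembl release 106, and StringTie and edgeR gave FPKM, a read level scaled to transcript length and library size. Versions and annotation filters are not given in the sources used here. The deposited FPKM cover 32520 Ensembl gene IDs in 15 columns used here; 3 further columns, named for 5 h, match no sample in the labels and entered no step. One 1 h column carries the letter B, which no 1 h sample title has, so it was assigned to the 1 h group only. Symbols were found for 29201 IDs in a table of gene names; 3319 had none. Many symbols are written in the human style and stand for several zebrafish copies. FPKM were summed over IDs that share a symbol, which gave 28103 genes; 1280 of the kept genes sum more than 1 ID, and such copies can share reads.

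FPKM values were whole multiples of what 1 read is worth, so reads could be recovered: all 20690 IDs above 0 in at least 2 libraries came out whole within a tolerance of 0.001 reads. The recovered totals were 12486844 to 15651535 reads per library. A gene of 2000 bases with 3 reads has an FPKM of 0.0958 to 0.12, and this floor covers counting error only. Genes with a wide use in cells were at 0 in some libraries, so a 0 is given as listed at 0.

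Genes with FPKM of at least 1 in at least 3 libraries were kept, 13051 in all. log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with all 15 libraries in 1 fit. Each time was compared with the control and with the time before it, 7 comparisons, plus a moderated F test over the 5 groups. Tests were two-sided, with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. Log2 differences are on the log2(FPKM + 1) scale and understate the change of low genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a comparison, for lists with at least 5 kept members. Of 32 lists, 26 were given by gene name and 6 by name pattern; lens crystallins had 3 kept members and were not tested. Some list names took their symbol from a table of aliases. The others were matched to symbols exactly, then without regard to case, then after removing a copy letter or number. Ribosomal protein kinases were kept out of the ribosomal list, and HBE1 was added to the haemoglobin list. These matching rules were set after the gene names were seen, from the names alone.

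The genes, lists, tests and most alternatives were fixed before the data were examined. Named genes were, per comparison with the control, the 10 highest and 10 lowest log2 differences among genes past the threshold whose libraries did not overlap and whose symbol was not a clone name; 5 and 5 for consecutive times. Where fewer passed, genes with the smallest p filled each direction to 5 and are said to have missed the threshold. Cytokine genes past the threshold and 6 fixed cytokines were named, and up to 4 members of each list. A few genes that the rule takes are not reported here, and they stay in the counts. Clone names were recognised by their first letters (LOC, ENSDARG, CABZ, CR, BX, CU, FO, FP). Read as written, this also takes out 66 kept genes that are not clones. FOS, FOSL1, FOSL2 and FOSB at 1 h and FOSL1 at 3 h would otherwise have been among the 10 highest, and they are named here as members of the immediate early list.

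Alternatives were a pseudocount of 0.1, no filter, median ratio scaling, quantile normalization, array quality weights, only the 2 groups compared, a replicate block, the submitters' threshold (log2 change beyond 1 with an unadjusted p under 0.05), and leaving out each library. Chosen after seeing the data were 1 value per gene ID, limma's voom on the recovered reads, and a fit without the 12 h libraries. On simulated data for 1 h against control, limma recovered 23 of 100 genes changed by a log2 of 2. It recovered 53 of 100 changed by 4, with 5 false calls in all. For 3 h it recovered 12 and 55 of 100, with 3 false calls. The changed genes were drawn from those with a mean of at least 100 reads, and genes were simulated apart. These rates therefore do not cover lower genes or genes that vary together. Recovery of reads was tested on 3000 simulated genes, and all 2993 that were above 0 in at least 2 libraries came out exact. Calls shared by 2 comparisons were set against unchanged groups, simulated 100 times with each gene's own spread and 100 times with genes that vary together as the residuals of the fit do, and the second kind was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.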

Results

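RNA was sequenced from venous tissue of uninjured zebrafish larvae and from venous thrombus tissue at 1, 3, 6 and 12 h after a laser injury, which the submitters describe as the start, peak, stable phase and regression of the clot. Each group had 3 libraries, with 12486844 to 15651535 recovered reads each. Between 11443 and 17422 genes were above 0 per library; the 1 h libraries had 11443, 12788 and 11771 and the control libraries 14288, 13988 and 14054. Muscle and mitochondrial transcripts were abundant in every group, and the 10 most abundant genes took 37.5% to 49.7% of FPKM. Pearson correlations of log2 values were 0.72 to 0.87 within groups and 0.67 to 0.85 between groups. The first 3 principal components held 15.9%, 14.2% and 9.93% of the variance, and the 3 h libraries had the highest scores on the first. Of 13051 genes, 211 differed among the 5 groups (limma moderated F, adjusted p under 0.05). That count was 121 without control replicate A, 91 without 3 h replicate A, and 128 and 134 without 6 h replicates A and B.

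The comparison of 1 h with the uninjured control was made to look at the first response to injury. No uninjured tissue was taken at 1 h, so handling and time of day cannot be told apart from injury here. SOCS3, a feedback inhibitor of cytokine signalling (2 summed IDs), rose from 9.78 ± 4.06 to 76.5 ± 19.4 FPKM (SD, n = 3 each; log2 difference 2.88 ± 0.44 SE, limma adjusted p = 0.010). HMOX1, the haem-degrading enzyme haem oxygenase, rose from 3.35 ± 2.06 to 47.9 ± 15.9 FPKM (log2 difference 3.57). BHLHE40, a transcriptional repressor of the clock, was listed at 0 in 2 control libraries and at 0.0265 FPKM in the other, and had 22 to 56.6 FPKM at 1 h. The libraries' captured regions are not tied to animals in the labels, so these p-values may be too small. The titin-binding muscle gene tcap (log2 difference 5.64), the nicotinamide riboside kinase nmrk2 (3.61), the polycomb gene cbx7a (3.46), PRELID3B, cplx4c and the mitochondrial MT-ND2 (1.46) and MT-ND4 (1.06) also rose. Lower at 1 h were ppdpfa, from 1616 ± 226 to 293 ± 55.9 FPKM (log2 difference -2.47), and CDC42EP3, an effector of the GTPase CDC42, from 79.1 ± 3.79 to 6.01 ± 4.89 FPKM (-3.81). spsb3b and ASB15 were listed at 0 in all 3 of the 1 h libraries, against 5.13 to 27.8 and 7.9 to 19.9 FPKM in the control. SLC25A48, golim4a, MTG1, tmem223 and TAMM41 were also lower, by log2 differences between -3.82 and -3.26.

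Among 39 immediate early genes, which are induced without new protein synthesis, 4 rose at 1 h, none fell and 35 did not pass; adjusted over the list alone, 11 passed. FOSL2 (log2 difference 3.45), FOS (4.64), FOSL1 (4.02) and FOSB (2.80) are subunits of AP-1. FOS had 103 ± 146 and FOSL1 25.5 ± 30.4 FPKM at 1 h (SD, n = 3). The mean level of immediate early genes relative to the control was 0.79, 2.38 and 0.49 in the 1 h libraries with columns A, B and C. Neural markers stood apart in column B as well, at -0.01, 2.36 and -0.28, and were higher at 1 h as a list (camera adjusted p = 0.00324, and adjusted p = 0.788 with an estimated correlation), but not without column B (camera adjusted p = 0.563). Other tissue in that library was not separated from its immediate early level. Without column B FOSL1 and FOSB missed the threshold (adjusted p = 0.0900 and 0.0839), FOSL2 and FOS passed, and the camera adjusted p of the list was 7.00e-06. Without control replicate A all 4 genes missed it, without control replicate B or C 1 of them passed, and FOSL1 missed it without column A and FOSB without column C. The list was higher than other genes (camera adjusted p = 1.45e-12), but not with an estimated correlation (adjusted p = 0.188). All 13 mitochondrially encoded mRNAs had positive differences and 2 passed; adjusted over the list alone, 13 passed (camera adjusted p = 3.78e-10, and adjusted p = 0.215 with an estimated correlation). Their mean rise was 1.31, 0.60 and 1.02 in columns A, B and C. The same libraries had 11443, 12788 and 11771 genes above 0, fewer than any control library, and an unnamed gene, ENSDARG00000080337, took 18.8%, 11.8% and 13.7% of FPKM there against 5.62% to 9.17% in the control, so the quality or composition of the libraries was not separated from the mitochondrial rise. In the heat shock and unfolded protein list none of 44 genes passed over all genes and 4 did adjusted over the list alone (camera adjusted p = 2.19e-06, and adjusted p = 0.188 with an estimated correlation); its smallest p was that of hsp70l, with a log2 difference of 3.61 and an adjusted p of 0.0748. Proteasome subunits were lower as a list, 34 of 39 members having negative or no difference, with 0 past the threshold and 3 adjusted over the list alone (camera adjusted p = 4.37e-06, and adjusted p = 0.188 with an estimated correlation). Notochord and cartilage markers, a sign of which tissue was captured, had a median log2 difference of -1.75 (camera adjusted p = 0.000314, and adjusted p = 0.423 with an estimated correlation, or 0.0844 without 1 h column A).

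In all, 16 genes were higher and 13 lower at 1 h. More were lower than higher with voom (33 higher, 60 lower) and with a pseudocount of 0.1 (16 higher, 24 lower), so which direction held more genes depended on the fit. The count of 29 fell to 7, 10 and 10 without control replicates A, B and C, fell to 12 without 1 h replicate A, and rose to 53 without the 1 h library whose column is named B. With only the 6 libraries compared, 0 genes passed in limma, against 1218 at an unadjusted p under 0.05 with all libraries and 93 with voom.

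**Figure D1:**
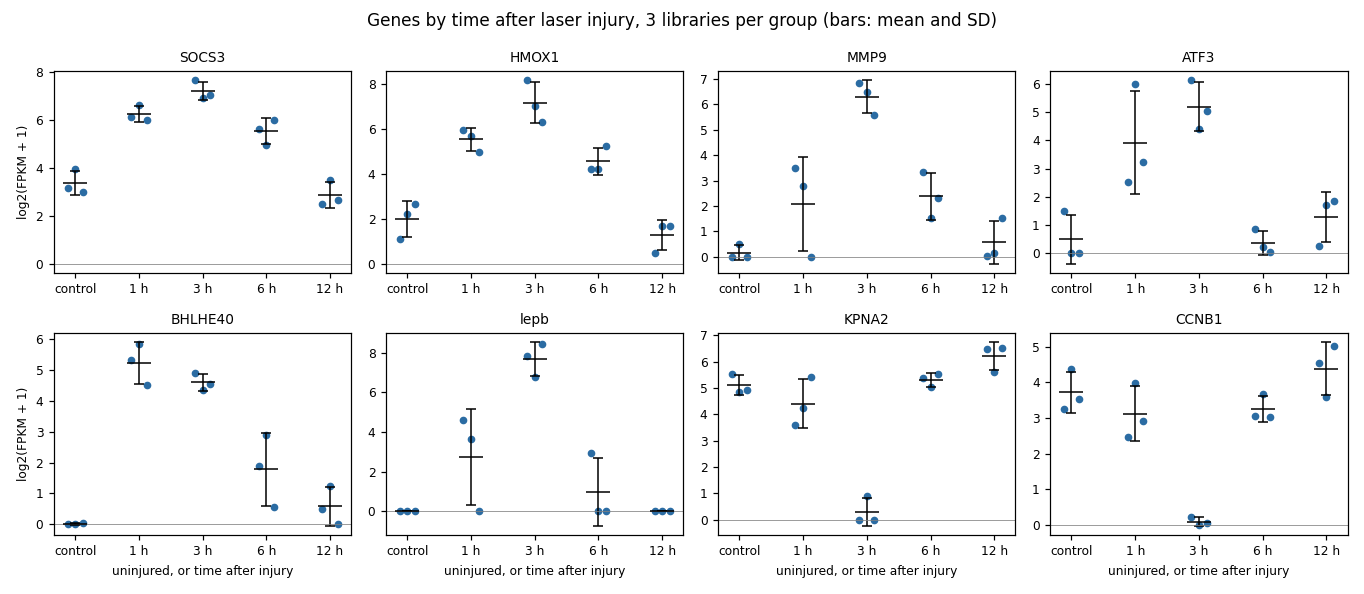
log2(FPKM + 1) of 8 genes (y axis) in the uninjured control and at 1, 3, 6 and 12 h after injury (x axis); points are the 3 libraries of a group, and bars are the mean and SD. SOCS3, HMOX1, MMP9, ATF3 and lepb have their highest mean at 3 h, BHLHE40 at 1 h, and KPNA2 and CCNB1 have their lowest mean at 3 h.

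At 3 h, the time the submitters give for the largest clot, 109 genes were higher and 72 lower than in the control. MMP9, a matrix-degrading gelatinase, had 82.4 ± 33.4 FPKM (SD, n = 3) at 3 h and 0, 0.413 and 0 in the control libraries (log2 difference 6.13, limma adjusted p = 0.000788). The leptin gene lepb was listed at 0 in all 3 control libraries and had 228, 108 and 346 FPKM at 3 h. HMOX1 rose to 167 ± 109 FPKM (log2 difference 5.20) and tcap to 1578 ± 102 FPKM (7.63). cbx7a (5.43), serpinb14 (4.71), the stress-induced transcription factor ATF3 (4.69) and ANKRD22 (5.10) rose too, as did SOCS1 (4.66), another inhibitor of cytokine signalling. Lower were KPNA2, an importin, from 34.2 ± 9.79 FPKM to 0, 0.867 and 0; CCNB1, cyclin B1 (log2 difference -3.63); MAD2L1, a spindle checkpoint gene (-3.98); cdkn1a, the cell cycle inhibitor p21 (-4.23); the chemokine ccl27a (-5.08); defbl1 (-4.36); NTMT2 (-4.06); ASB15 (-3.94); and APOBEC2 (-3.79). NDUFAB1, the mitochondrial acyl carrier protein, had 0.295, 63.1 and 0.664 FPKM at 3 h against 110, 110 and 137 in the control.

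Among immediate early genes 11 of 39 rose at 3 h and none fell, and 16 did adjusted over the list alone (median log2 difference 1.40; camera adjusted p = 3.83e-12, and adjusted p = 0.136 with an estimated correlation). FOSL2 (3.87), FOSL1 (5.56), fosl1b (3.24) and GADD45B (2.94) were among them. Of 21 glucocorticoid response genes 3 rose, and 12 did adjusted over the list alone (median 1.88; camera adjusted p = 7.1e-11, and adjusted p = 0.122 with an estimated correlation); FOXO1 had a log2 difference of 2.51. Oxidative stress genes rose in 5 of 37 cases, HMOX1, the ferritin gene fthl31 (4.46), prdx1 (3.29) and gsto2 (2.82) among them (11 adjusted over the list alone; camera adjusted p = 7.01e-05, and adjusted p = 0.136 with an estimated correlation). Of 44 heat shock genes 4 rose: hspb9 (4.41), hspb6 (3.06), hsp70l (3.90) and hsp70.3 (4.35), and 7 did adjusted over the list alone (camera adjusted p = 0.000186, and adjusted p = 0.136 with an estimated correlation). Of 37 hypoxia and glycolysis genes 2 rose, PFKFB3 (4.22) and PDK2 (3.83), and adjusted over the list alone 7 were higher and 1 lower (camera adjusted p = 0.00222, and adjusted p = 0.158 with an estimated correlation).

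Cell cycle genes were lower at 3 h, with 3 of 42 past the threshold and 7 adjusted over the list alone (median -1.04; camera adjusted p = 7.25e-07, and adjusted p = 0.136 with an estimated correlation). hmgb2b (-2.48), CCNB1 and UBE2C (-3.20) passed. Against the control the same list was higher at 1, 6 and 12 h (medians 0.12, 0.48 and 0.57; camera adjusted p = 0.0251, 0.00272 and 0.0015, and adjusted p = 0.606, 0.718 and 0.78 with an estimated correlation), with 0 genes past the threshold at these times and 3 higher at 12 h adjusted over the list alone. These 3 calls ended without control replicate C (0.434, 0.161 and 0.136), the first also without 1 h column A (0.0512) or C (0.487) and the last without 12 h replicate A (0.109), while the call at 3 h held without each control or 3 h library. Proteasome subunits PSMA3 (-1.27), PSMB4 (-1.45) and PSMB7 (-1.16) fell, 3 of 39, and 10 adjusted over the list alone (camera adjusted p = 3.12e-07, and adjusted p = 0.136 with an estimated correlation). Neutrophil markers rose in 3 of 18 cases, MMP9, mmp13a (4.40) and adam8b (3.00); these proteases are also made by other cells (camera adjusted p = 0.000634, and adjusted p = 0.136 with an estimated correlation). Adjusted over the list alone, 4 neutrophil markers were higher and 1 lower. Endothelial markers had a median of -0.63, with 0 of 37 past the threshold and 3 lower adjusted over the list alone (camera adjusted p = 0.00674, and adjusted p = 0.136 with an estimated correlation, or 0.0520 without 3 h replicate B). Epidermis markers ITGB4 (2.96) and ahnak (2.22) rose, 2 of 36, also 2 adjusted over the list alone (camera adjusted p = 0.000657, and adjusted p = 0.479 with an estimated correlation, or 0.0857 without 3 h replicate A). The mean epidermis level relative to the control was 1.63, 1.08 and -0.85 in 3 h replicates A, B and C, so it did not move one way.

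Genes of haemostasis were examined because the tissue is a clot. In the list of anticoagulants and fibrinolysis 2 of 9 members rose at 3 h, with the plasminogen receptor subunit ANXA2 (3.59) among them, and 3 did adjusted over the list alone (camera adjusted p = 0.00183, and adjusted p = 0.136 with an estimated correlation). None of 8 kept coagulation factor genes passed at 3 h, with 2 higher adjusted over the list alone (camera adjusted p = 0.356). Of 14 thrombocyte markers 1 was past the threshold at 3 h (camera adjusted p = 0.188).

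The count of 181 at 3 h was 46, 59 and 103 without control replicates A, B and C, and 60 and 109 without 3 h replicates A and B. With only the 6 libraries compared it was 30, and with no filter it was 94.

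Of 25 kept cytokine and chemokine genes, 2 passed at 3 h and 0 at 1, 6 or 12 h; adjusted over the list alone, 1 was higher at 1 h, 5 were higher and 1 lower at 3 h, 2 were higher and 1 lower at 6 h, and 1 was higher at 12 h. The neutrophil attractant cxcl8b.1 rose from 2.08 ± 3.61 to 44.2 ± 15.9 FPKM (SD, n = 3; log2 difference 4.49 ± 1.02 SE, limma adjusted p = 0.0376) at 3 h, and ccl27a fell. cxcl8b.1 already had 29.4, 77.2 and 23.2 FPKM at 1 h, with a log2 difference of 4.32 that missed the threshold (adjusted p = 0.102). The list as a whole did not pass at 3 h (camera adjusted p = 0.061). il1b, the gene of interleukin 1 beta, was listed at 0 in all 3 control libraries and had 5.87, 0.857 and 1.07 FPKM at 3 h. cxcl8a had 1.65, 1.87 and 0 FPKM in the control 16.9, 4.23 and 4.17 at 3 h, and its highest mean at 12 h, with 23.9, 8.61 and 14.6. Its log2 differences of 2.00 at 3 h and 2.98 at 12 h missed the threshold (adjusted p = 0.268 and 0.334). tnfa was listed at 0 in all 15 libraries, and il6 was above 0 in 1 of them, with 4.02 FPKM in 12 h replicate C. il10 was above 0 in 3 libraries, and il11a in 4, with 19.7 FPKM in 3 h replicate C.

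At 6 h, when the clot is stable per the submitters, 0 genes passed in limma against the control, with 721 at an unadjusted p under 0.05 (5.52% of genes) and 1 with voom. The smallest p among genes that missed the threshold belonged to cbx7a (log2 difference 3.35), tcap (4.55), arpp21 (3.61), XXYLT1 (2.25) and rorcb (2.97) on the higher side. On the lower side they belonged to metrnlb (-2.67), nr1d4b (-2.70), fbxo2 (-2.20), serinc2 (-2.13) and kcnip4b (-1.54). The heat shock and unfolded protein list was higher: 38 of 44 members had positive differences, 0 passed over all genes and 9 did adjusted over the list alone (median 0.99; camera adjusted p = 9.66e-13, and adjusted p = 0.0377 with an estimated correlation). PDIA4 (2.59), HSPA5 (1.88), HYOU1 (2.52) and calr3b (1.84), chaperones of the endoplasmic reticulum, had the smallest p and missed the threshold. Epidermis markers were lower as a list (median -0.88; camera adjusted p = 0.000385, and adjusted p = 0.718 with an estimated correlation, or 0.0764 without 6 h replicate A).

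At 12 h, during regression, 0 genes passed in limma against the control, with 992 at an unadjusted p under 0.05 and 8 with voom. The smallest p belonged to CHTF8 (2.37), HPSE2 (3.23), the fin fold genes and1 (4.80) and and2 (3.92), and st6galnac1.1 (2.92) on the higher side. On the lower side they belonged to tsr1 (-1.92), kcnip4b (-1.36), crispld1b (-2.32), tmem45a (-2.40) and SFRP5 (-2.40), and all 10 missed the threshold. Neural markers had a median of 1.61, with 0 of 27 past the threshold and 3 adjusted over the list alone (camera adjusted p = 3.81e-05, and adjusted p = 0.78 with an estimated correlation). Their mean level relative to the control was 0.26, 4.14 and 0.45 in 12 h replicates A, B and C, and without replicate B the camera adjusted p was 0.959. Skeletal muscle markers were lower (median -0.45; camera adjusted p = 1.15e-09, and adjusted p = 0.78 with an estimated correlation), with 0 of 41 past the threshold.

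**Figure D2:**
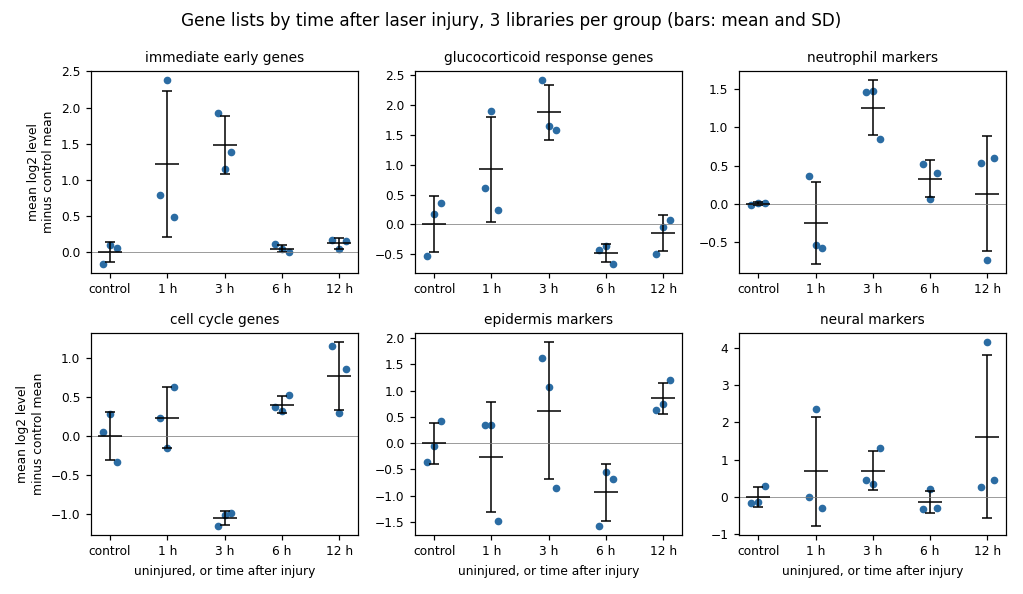
Mean log2(FPKM + 1) of the kept members of 6 gene lists minus the mean of the control libraries (y axis) by group (x axis); points are the 3 libraries of a group, and bars are the mean and SD. Cell cycle genes are lowest at 3 h, and 12 h replicate B stands apart in neural markers at 4.14.

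Consecutive times were compared to follow the clot from one phase to the next. From 1 to 3 h, 17 genes rose and 15 fell. lepb (log2 difference 4.93), MMP9 (4.21), tmem223 (3.48) and SLC10A7 (3.46) were among the first, and NDUFAB1 (-4.85), defbl1 (-4.64), the DNA replication gene pclaf (-4.60), KPNA2 (-4.11) and the kinetochore gene spc24 (-3.90) led the second. Cell cycle genes fell as a list, with 3 of 42 past the threshold and 13 adjusted over the list alone (camera adjusted p = 4.4e-15, and adjusted p = 0.0725 with an estimated correlation). The count of 32 was 2 with array weights, 2 without the 12 h libraries, 0 with only the 6 libraries compared and 67 with median ratio scaling, of which 65.7% were higher against 53.1% in the fit reported. Leaving out a library moved it to 21 without 1 h replicate A or C, 54 without the 1 h library whose column is named B, and 16, 7 and 88 without 3 h replicates A, B and C.

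From 3 to 6 h, 67 genes rose and 78 fell, and 85 of these had changed the other way between control and 3 h. KPNA2 (log2 difference 5.01, limma adjusted p = 0.000276), NDUFAB1 (4.78), ppil3 (4.42), MAD2L1 (4.39) and pclaf (4.19) rose. lepb (-6.70), the tight junction gene and epidermis marker cldnb (-6.37), UCP1 (-5.56), SOCS1 (-5.49) and ANKRD22 (-5.18) fell. All 42 cell cycle genes had positive differences, 5 passed and 15 did adjusted over the list alone (median 1.35; camera adjusted p = 5.13e-14, and adjusted p = 0.0492 with an estimated correlation). Glucocorticoid response genes fell, 3 of 21 over all genes and 16 adjusted over the list alone (median -2.09; camera adjusted p = 2.77e-14, and adjusted p = 0.0461 with an estimated correlation). Immediate early genes fell in 7 of 39 cases, 15 adjusted over the list alone (camera adjusted p = 7.44e-12, and adjusted p = 0.139 with an estimated correlation). Epidermis markers fell as well, 1 of 36 over all genes and 6 adjusted over the list alone (camera adjusted p = 2.76e-10, and adjusted p = 0.252 with an estimated correlation). Their mean level against the control was 1.63, 1.08 and -0.85 in 3 h replicates A, B and C and -1.57, -0.56 and -0.69 at 6 h. The level of 3 h replicate C thus lay within the 6 h range. Both comparisons use the 3 h libraries. Unchanged groups simulated 100 times shared 0 such genes, also when genes varied together as in the data. An adjusted threshold leaves few calls in unchanged groups, so this could not show how many of the 85 come from the shared libraries. Independent lists would share 1.02, and part of the excess over that may come from the shared libraries. The covariance of log2 differences over genes was -0.825 (r = -0.73), against -0.265 (r = -0.498) for simulated genes that vary apart and between -0.975 and 0.135 for genes that vary together, so it does not separate the return from the sharing. The count of 145 was 43 and 239 without 3 h replicates A and C, 40, 42 and 54 without 6 h replicates A, B and C, and 7 with only the 6 libraries compared.

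From 6 to 12 h, 8 genes rose and 5 fell. The actinodin genes and1 (5.42), and2 (4.39) and and3 (6.01), which form the fibres of the fin fold, rose with col4a5 (2.96) and serinc2 (2.90). tcap (-5.38), arpp21 (-3.43), HMOX1 (-3.29) and SOCS3 (-2.65) fell, and crispld1b (-3.03) missed the threshold. Epidermis markers had positive differences in 35 of 36 cases, with 0 past the threshold and 16 adjusted over the list alone (median 1.98; camera adjusted p = 6.76e-07, and adjusted p = 0.538 with an estimated correlation). The count of 13 was 0 without 6 h replicate A or C or 12 h replicate C, 1 without 6 h replicate B and 6 without 12 h replicate A. It was 15 with quantile normalization and 7 with median ratio scaling, of which 33.3% and 28.6% were higher, against 61.5% in the fit reported.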

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

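The tests of matched lists, time of day, epidermis at 12 h and neural genes were chosen after the results they bear on were seen.

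These genes had an effect against the control that differed between consecutive times by limma's test of the difference. They were taken from the genes named at 1 h or 3 h against the control, and the tests reuse the libraries of those times. That choice favours such differences, so the list is no independent evidence of a change between times. From 1 to 3 h the log2 difference was 3.48 for tmem223, 4.93 for lepb, 4.21 for MMP9, -4.11 for KPNA2, -4.85 for NDUFAB1, -4.64 for defbl1 and -3.02 for CCNB1. From 3 to 6 h it was -6.70 for lepb, -3.90 for MMP9, -2.63 for HMOX1, -5.18 for ANKRD22, -4.82 for ATF3 and -5.49 for SOCS1. In the same step it was 5.01 for KPNA2, 4.78 for NDUFAB1, 4.39 for MAD2L1, 3.21 for ASB15, 3.56 for APOBEC2 and 3.16 for CCNB1.

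The first pattern is the set of 109 genes higher at 3 h. With the epidermis level of each library in the fit their median log2 difference was 3.14, against 3.29 before, and 93 stayed past the threshold. The genes were picked for large differences and the level moved less, so the fit could hardly remove them. In 3 h replicate C the level against the control was -0.85, lower than in every control library. No gene called at 3 h overlapped the control libraries, but the same held for the calls of every other comparison. The calling thus nearly fixes this outcome, so it cannot speak for or against more epidermis. More epidermis, handling and time of day stay open. Of 27 circadian clock genes 3 passed at 3 h, BHLHE40 and PER3 higher and nr1d4b lower. Captured tissue other than epidermis was not tested for these genes. In 3 h replicates A, B and C the notochord and cartilage level against the control was -2.68, -1.09 and -0.93. The endothelial level was -0.40, -0.83 and -0.74, the neutrophil level 1.46, 1.47 and 0.85, and the skeletal muscle level -0.38, -0.19 and 0.06. No uninjured tissue of the same clock time was compared. Injury, handling, time of day and the mix of captured tissue therefore cannot be told apart.

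The second pattern is the lower level of cell cycle genes and proteasome subunits at 3 h. Each list's median, -1.04 and -0.96, lay at the 0.01 percentile of 10000 random lists matched on abundance and again of lists matched on gene length, the smallest value that many lists can give. Genes of like abundance or length did not fall as far, with random medians of -0.16 and -0.21 for abundance. Random lists ignore the correlation between genes, and a difference in the cells captured stays open, as does an effect of the injury. The 3 h libraries had 12857, 13074 and 13282 genes above 0, fewer than the control libraries with 13988 to 14288. The 1 h libraries had fewer still, 11443 to 12788. There the proteasome list was lower and the cell cycle list was not.

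The third pattern is the tissue in the 12 h captures. The 10 most abundant epidermis genes had a median log2 difference of 2.57 from 6 to 12 h, but they belong to the list whose rise was seen first, so this decides nothing. The mean epidermis level against the control was -1.57, -0.56 and -0.69 at 6 h and 0.64, 0.74 and 1.19 at 12 h, so part of the step is the lower level at 6 h. More epidermis at 12 h, less at 6 h and a change within the cells cannot be told apart, since no test here separates them. Neural markers may come from neural tissue in 1 library: in the other 12 h libraries their mean level against the control was 0.35. Regression of the clot was not separated from the place of capture.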

How the results depend on the processing

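Each comparison held few libraries, and the counts moved with the settings; the cause was not tested except where fewer libraries or genes entered. Without a filter 16, 94, 6, 18 and 69 genes passed at 1 h, 3 h and 12 h against control, 3 h against 1 h and 6 h against 3 h, and 97 differed among the 5 groups. A pseudocount of 0.1 left 0 at 12 h against 6 h. Median ratio scaling gave 67 at 3 h against 1 h and 7 at 12 h against 6 h. Array weights gave 324 at 3 h and 13 at 6 h against control, 2 at 3 h against 1 h, 285 at 6 h against 3 h and 32 at 12 h against 6 h. With only the 2 groups compared, 0 and 30 passed at 1 h and 3 h against control, 0 at 3 h against 1 h, 7 at 6 h against 3 h and 0 at 12 h against 6 h. The submitters' threshold gave 1144, 1750, 699 and 941 against control at 1, 3, 6 and 12 h, then 1419, 1854 and 1392 for consecutive times, and 2101 among the 5 groups.

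Of the fits chosen after seeing the data, voom gave 93, 328, 1 and 8 against control, 77 at 3 h against 1 h, 25 at 12 h against 6 h and 495 among the 5 groups; every gene called in the fit reported kept its sign. Of those genes 21 of 29 and 136 of 181 passed with voom at 1 h and 3 h against control, but 12 of 32 at 3 h against 1 h, 68 of 145 at 6 h against 3 h and 3 of 13 at 12 h against 6 h. Without the 12 h libraries 3 genes passed at 6 h against control and 2 at 3 h against 1 h. One value per gene ID moved no count by over 1.5 times. The direction with more genes turned in some fits. At 1 h, 16 were higher and 24 lower with a pseudocount of 0.1, 33 and 60 with voom, and 397 and 747 by the submitters' threshold, which gave 778 and 972 at 3 h. At 3 h against 1 h it was 13 and 14 with that pseudocount, 8 and 10 with no filter and 0 and 2 with array weights. At 6 h against 3 h it was 74 and 56 with that pseudocount, 145 and 140 with array weights and 998 and 856 by the submitters' threshold.

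Leaving out each library gave 7 to 53 genes at 1 h, 46 to 209 at 3 h, 0 to 0 at 6 h and 0 to 1 at 12 h against control. It gave 7 to 88 at 3 h against 1 h, 40 to 239 at 6 h against 3 h, 0 to 14 at 12 h against 6 h and 91 to 314 among the 5 groups. No called gene changed sign in these fits.

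Same-letter libraries did not deviate together in 26 pairs, where the correlation ran from -0.155 to 0.134. The 1 h column named B was not matched to a sample, so its pairs with B libraries were counted among the 64 other pairs. Over these it ran from -0.163 to 0.211, and the 0.211 was that column with 12 h replicate B. With replicates B of the control, 3 h and 6 h that column had -3.72e-05, -0.0486 and 0.00872. That the main fit takes no letters as pairs was set beforehand. With the replicate block 9 genes passed at 1 h (2 higher, 7 lower), 1 at 6 h, 19 at 3 h against 1 h and 3 at 12 h against 6 h. The 1 h column named B had a block of its own, so only columns A and C informed the 1 h differences in that fit. Its 1 h counts thus mix the loss of a library with the use of letters.

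Quantile normalization moved the median log2 difference of all genes at 12 h against control from 0.32 to -0.01, and median ratio scaling moved it to 0.10. With median ratio scaling the 12 h differences of RPL38 and RPS10 turned to -0.0084 and -0.073. Without 12 h replicate B, 12 h against 6 h turned to 0.0072 for hbae1.3, 0.045 for hbae3 and 0.17 for hbae1.1; without 12 h replicate A they were -2.37, -2.06 and -2.19. Without replicate B the erythrocyte list turned upward, with adjusted p = 0.344 against control and 0.961 against 6 h. Over all left-out libraries its adjusted p ran from 2.79e-08 to 0.395 against control and from 1.18e-08 to 0.961 against 6 h. With fry, the ribosomal and respiratory chain lists at 12 h turned upward (adjusted p = 0.952 and 0.96). Among 1079 list results under alternatives 824 kept their side of the threshold and direction, 251 lost the call and 4 reversed.

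The 10 splits of 6 libraries are too few for a share under 0.05. The real counts and the highest of the other splits were 29 and 2, 181 and 4, 0 and 2, and 0 and 32 against control at 1, 3, 6 and 12 h. For consecutive times they were 32 and 18, 145 and 4, and 13 and 1. As many genes as the real count were called in 1, 1, 10, 10, 1, 1 and 1 of the 10 splits. The 32 came from a split of the control and 12 h libraries other than the groups, and its cause was not tested. Among 100 random splits into 5 groups only the real one, 1 of 100, reached 211 genes, and the highest other had 24. The groups thus differ by more than random sets of independent libraries do. Libraries of a group may share an animal, and the splits cannot exclude that as the source.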

Other observations

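Genes and lists outside the comparisons above also moved. Of 26 erythrocyte markers 0 passed at any time against the control; as a list they were higher at 1 h (median 0.47, camera adjusted p = 0.00472, and adjusted p = 0.748 with an estimated correlation). That call ended without control replicate C (0.0629) or 1 h replicate A (0.0844). The list was lower at 3 h than at 1 h (camera adjusted p = 0.00272, and 0.624 with an estimated correlation), at 12 h than in the control (0.0313, and 0.78) and at 12 h than at 6 h (0.00318, and 0.686). The mean level against the control was 1.01, -1.53 and 0.03 in 12 h replicates A, B and C. The fall from 1 to 3 h missed the threshold without 1 h replicate A (0.0501) or 3 h replicate B (0.117). Both 12 h calls ended without 12 h replicate B (0.344 and 0.961), the first also without control replicate B (0.395) and the second without 6 h replicate C (0.162). Clock genes were higher at 3 h as a list (median 1.00; camera adjusted p = 0.000436, and adjusted p = 0.147 with an estimated correlation), with BHLHE40 (log2 difference 4.59) and PER3 higher and nr1d4b (-2.70) lower. Of 15 interferon response genes 0 passed at 3 h (camera adjusted p = 0.0447, and adjusted p = 0.232 with an estimated correlation), and the list call ended without control replicate B (0.104) or C (0.0627) or 3 h replicate A (0.0993) or B (0.113). Of 43 NF-kB and inflammatory response genes 1 rose at 1 h and 3 at 3 h, SOCS3, il4r.1 (3.86) and SOCS1, and the list was higher at 3 h (median 0.59, camera adjusted p = 2.36e-05, and adjusted p = 0.136 with an estimated correlation). Notochord and cartilage markers were lower at 3 h (median -1.85, camera adjusted p = 0.000518, and adjusted p = 0.28 with an estimated correlation), with SOX9 past the threshold. Macrophage markers did not pass as a list at 3 h (camera adjusted p = 0.58). Nor did fibroblast and matrix genes (0.228), haemoglobin genes (0.46), liver, gut and pancreas markers (0.403), nuclear-encoded respiratory chain genes (0.142), endothelial activation genes (0.0875) or skeletal muscle markers (0.353), all as camera adjusted p at 3 h. Complement genes, of which 0 of 6 passed, p53 pathway genes, neural markers, mitochondrially encoded mRNAs and ribosomal proteins were higher as lists at 3 h (camera adjusted p = 0.0102, 0.0293, 0.00936, 0.000266 and 0.00315), and none was with an estimated correlation (adjusted p = 0.232, 0.321, 0.599, 0.306 and 0.7). Of these 3 h calls, that of neural markers ended without 3 h replicate C (0.197), whose mean level against the control was 1.32, with 0.45 and 0.36 in replicates A and B. Complement genes missed the threshold without 3 h replicate B (0.0931), ribosomal proteins without 3 h replicate A (0.0694), and p53 pathway genes without control replicate C (0.0894) or 3 h replicate A (0.167) or C (0.0640). At 12 h camera put the ribosomal and respiratory chain lists lower than other genes, while their medians were 0.05 and 0.03, since the median of all genes was 0.32 (camera adjusted p = 0.0489 and 0.0132, and adjusted p = 0.827 and 0.78 with an estimated correlation). The ribosomal call ended without control replicate A (0.129) or C (0.136) or 12 h replicate B (0.959), and the respiratory chain call without control replicate A (0.0502) or B (0.371) or 12 h replicate C (0.166).

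The 1 h and 3 h comparisons shared 17 genes called in the same direction, 11 higher and 6 lower. Independent lists would share 0.134 and 0.0717. Unchanged groups simulated 100 times against the same controls shared 0, or at most 5 when genes varied together as in the data. Few calls arise in unchanged groups at an adjusted threshold, so this does not show how many of the 17 come from the shared controls. Part of the excess over independent lists can come from the shared controls, which are too few to split. The covariance of log2 differences over genes was 0.496, against 0.267 for simulated genes that vary apart, while the correlations were 0.527 and 0.501. For genes that vary together the simulated covariance ran from -0.126 to 0.782, which takes in the observed one.

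Of the 72 genes lower at 3 h, 36 had at least 1 of the 3 h libraries at 0 and 11 had all 3 at 0. An unnamed gene, ENSDARG00000080337, took 5.62%, 5.68% and 9.17% of FPKM in the control libraries and 18.8%, 11.8% and 13.7% in the 1 h libraries. It took 13.4%, 13.9% and 12.4% at 3 h, 11.3%, 8.60% and 7.90% at 6 h, and 10.4%, 6.19% and 10.0% at 12 h.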
